A study of Mus musculus with 2 samples.

How the data were processed

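The data were the gene and transcript quantifications of 2 polyA RNA libraries of mouse liver at 12.5 days, a single group of 2 biological replicates per the labels. Per the labels, RNA was extracted with the mirVana kit, 10 ng was used with ERCC spike-ins, cDNA was made with the SMARTer Ultra Low kit and libraries were tagmented with Nextera. The expected counts are as deposited and stand for reads divided among genes or transcripts by the authors' quantification, so they need not be whole numbers. The TPM values are as deposited, made by the authors from those counts and effective lengths, per the file headers. The posterior SD of the counts and the posterior mean TPM are as deposited and per the file headers describe the uncertainty of that division. The aligner, the quantifier and their versions are not given in the sources used here, and neither is the use of strand. The notes deposited with each library give the mm10 assembly and, for each table, the annotation GENCODE M4 or M21. Alignments and signal tracks were not used here.

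Each library had a gene and a transcript quantification under both annotations, and M21, the more recent, was used throughout except where M4 is named. The M21 gene quantification held 81881 entries, of which 55536 carried Ensembl gene identifiers and 96 were spike-ins. The summed expected counts were 38293265 and 35399872. A further 26248 entries had bare numbers as identifiers, which the sources do not explain, and they were left out of the gene analyses. Spike-ins were kept out of library sizes. Spike-in TPM took 4.99% and 5.40% of all TPM, so gene TPM values are relative to totals that include them. Gene names, types and coordinates came from the GENCODE M21 table, which held 55450 of the identifiers. The other 86 lie on unplaced scaffolds and have no name here.

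The comparisons, gene lists, alternatives and naming rule were fixed before the data were examined, except where an addition is named. For levels, TPM was averaged over the 2 libraries, and for each list the genes at 1, 10 and 100 TPM and the median were counted. Each list median was ranked among 10000 random lists of protein-coding genes of equal size (seed 20240). The 31 lists were embryonic globins, adult globins, red cell regulators, red cell membrane, haem synthesis and iron, hepatoblast, plasma proteins, mature hepatocyte, bile duct, stem and progenitor, megakaryocyte, macrophage, granulocyte, mast cell, lymphoid, endothelium, mesenchyme, mesothelium, gut with pancreas and lung, cardiac, neural, skeletal muscle, cell cycle, imprinted growth, niche factors, immediate early with heat shock, glycolysis with hypoxia, sterol synthesis, sex-linked, mitochondrial and histone genes. They were drawn from general knowledge of the cell types and held 435 entries of 428 genes. Of the entries 432 were matched, and Hbb-b1, Hbb-b2 and Ahsp found no gene of that name. The genes Angpt1, Aqp1, Cxcl12, Dlk1, Gata2 and Hgf each stood in 2 lists.

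The replicate libraries were scaled with the TMM method of edgeR 4.0.16, and the common dispersion was estimated by edgeR with an intercept-only design. Genes with a mean expected count of at least 10 were compared with a prior count of 0.5. A gene was counted as differing where the ratio passed 2-fold and the exact 95% binomial interval of the split of its counts, rounded to whole numbers, excluded the scaled split. A test on the reads of 2 libraries compares libraries, not conditions. List medians of the log2 ratio were ranked among 10000 random lists matched in 20 bins of mean expression, and a list counted as outside below the 2.5 or above the 97.5 percentile. For the annotations, genes present under both and at 1 TPM or more under either were compared as log2((TPM + 1)/(TPM + 1)), and a gene differed where the ratio passed 1.5-fold in both libraries in the same direction. Transcript shares were taken over the summed TPM of each of 25 genes, 1 of which has a single annotated transcript and was left out of the counts of genes, and starts within 50 bases were grouped. Genes with identical or overlapping copies were left in and are called uncertain.

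Genes were named by rule. These were the 10 with the highest mean TPM, the 4 highest members of each list with up to 2 members under 1 TPM, all globin and sex-linked genes, and the differing genes with a mean of at least 100 counts and the largest ratios, up to 6 in each direction. The 5 largest differences in each direction between annotations among genes at 10 TPM or more, and the genes with at least 2 transcripts at 10% in both libraries, were also named, with Pklr, Alad, Hnf4a and Pkm in any case. Some genes that the rule selects are not reported here. Fixed alternatives were DESeq2 1.42.0 size factors, spike-in and total count scaling, other count filters, pseudocounts of 0.1 TPM, rescaled TPM, posterior mean TPM, the M4 annotation, summed in place of median TPM and each library alone. Random lists matched also on transcript length in 10 bins, protein-coding genes only, and list members with a posterior SD under 5% were added after seeing the data. A list of 24 further muscle genes and a list of 15 skin, cartilage and limb genes were also drawn up afterwards, before their own values were read. Lum was dropped from the latter before its result was read because a fixed list already held it.

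The calling steps were tried on simulated counts with 200 changed genes and a coefficient of variation of 0.05. They recovered 4.5% of genes changed 1.5-fold, 90.5% at 2.5-fold and 97.5% at 4-fold, with 97, 78 and 78 false calls among 17360, 17345 and 17390 genes. With no changed genes there were 104 false calls among 17341, of which 0 had a mean of at least 100 counts, and the recovered coefficient was 0.0494. Random lists without change fell outside in 5.5%, 4.5% and 4.0% of 200 trials. Calls at low counts therefore include false ones, and differing genes outside the fixed lists are named only from a mean of 100 counts. Members of the fixed lists are named from a mean of 10 counts, so their calls under 100 counts can be false. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.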

Results

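Polyadenylated RNA was measured by RNA sequencing in liver of mouse embryos at 12.5 days of development, when the foetal liver is a site of blood formation and holds blood cells beside the cells of the liver itself. Livers of male and female B6NCrl embryos were pooled, and pools of 120 and 88 embryos gave replicate 1 and replicate 2. Each library was made from 10 ng of RNA with synthetic ERCC spike-in RNAs added. The expected counts summed to 38293265 in replicate 1 and 35399872 in replicate 2, and protein-coding genes held 92.0% of the counts. Of 55536 annotated genes, 13566 and 13622 reached 1 TPM, and 11931 and 11990 of these were protein-coding. TPM divides each count by effective length and then by the sum of all such length-scaled values in the library. Values below are the mean ± SD of the 2 libraries (n = 2) unless a single library is named, and coordinates are on mm10 with the GENCODE M21 annotation. The labels give a single tissue and stage, so the comparisons are between gene programmes within this tissue, between the 2 pools, and between the 2 annotations with which each library was quantified. With a single group no p-value was computed. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules, and a count of 0 allows up to 3 counts in a library.

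Red cell globins were the most abundant transcripts in the tissue. The adult alpha globin gene Hba-a2 (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298) led with 102648 ± 638 TPM, followed by the adult beta globin gene Hbb-bs (ENSMUSG00000052305.6, chromosome 7, 103826534 to 103828096) with 60236 ± 1301 TPM. Hba-a1 (ENSMUSG00000069919.7, chromosome 11, 32283511 to 32284465) had 44847 ± 743 TPM, and Hbb-bt (ENSMUSG00000073940.3, chromosome 7, 103812524 to 103813996) had 32168 ± 425 TPM. The embryonic gene Hbb-y (ENSMUSG00000052187.4, chromosome 7, 103851749 to 103853216) came next with 8709 ± 541 TPM. The other members of the 10 most abundant genes were CT010467.1, a ribosomal RNA gene on chromosome 17 with 6746 ± 188 TPM, the ferritin light chain gene Ftl1 with 6686 ± 292 TPM, the actin gene Actb with 6603 ± 116 TPM, Gm22133 with 6338 ± 117 TPM and the signal recognition particle RNA gene Rn7s1 with 6077 ± 203 TPM. These 10 genes took 28.1% ± 0.296 of all TPM. Gm22133 is annotated as a microRNA inside Ftl1 (chromosome 7, 45458089 to 45458197), and its TPM rested on 2097 and 1892 counts over an effective length of 10 bases, so its level is uncertain.

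The embryonic and adult globin genes were compared because primitive and definitive red cells differ in the globins they make. Adult-type genes held most of the globin message, and the embryonic share was larger on the beta side than on the alpha side. Hbb-y and Hbb-bh1, the embryonic beta-like genes, made up 9.68% ± 0.359 of beta-like globin TPM, with 9.43% in replicate 1 and 9.94% in replicate 2. Hba-x, the embryonic alpha-like gene (chromosome 11, 32276400 to 32278116), had 1608 ± 69.1 TPM and made up 1.08% ± 0.0359 of alpha-like globin TPM. Hbb-bh1 (chromosome 7, 103841637 to 103843164) had 1203 ± 49.99 TPM, so that Hbb-y exceeded it 7.23-fold ± 0.149. The adult alpha genes summed to 147496 ± 1381 TPM and the adult beta genes to 92404 ± 1726 TPM, and the alpha-like genes together stood at 1.46 ± 0.0188 times the beta-like genes. All 7 globin genes together took 25.1% ± 0.377 of TPM but 10.5% ± 0.176 of expected counts, since their transcripts are short. The adult copies are near-identical, so the division of reads within the Hba-a1 and Hba-a2 pair and within the Hbb-bs and Hbb-bt pair is uncertain, and shares were taken over their sums.

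**Figure D1:**
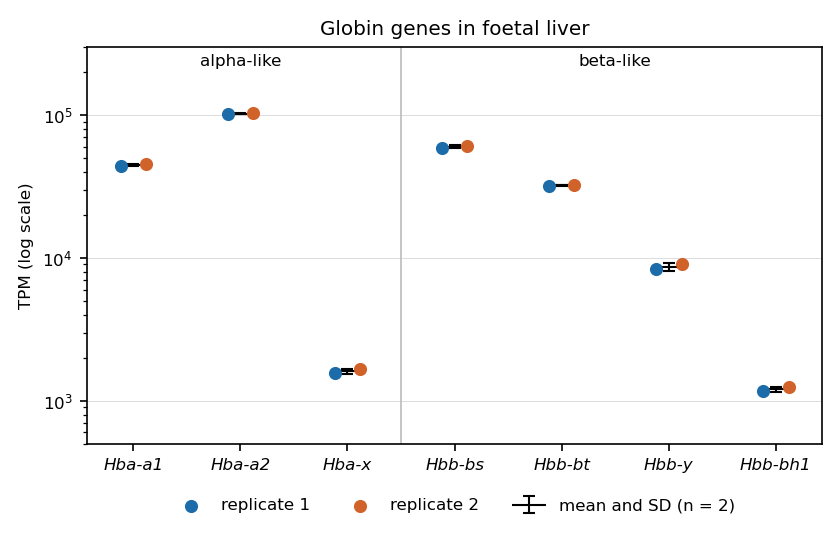
TPM of the 7 globin genes on a log axis, with a point for each of the 2 libraries and a bar at their mean. The adult genes lie between 32168 TPM (Hbb-bt) and 102648 TPM (Hba-a2), and the embryonic genes between 1203 TPM (Hbb-bh1) and 8709 TPM (Hbb-y).

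The blood-forming and hepatic programmes were compared because both lineages share the organ at this stage. Which programme stood higher depended on the lists and on the summary. The pooled median over 44 regulators, membrane proteins and haem synthesis genes of the red cell was 157 ± 3.94 TPM, against 61.9 ± 1.66 TPM over 53 hepatoblast and plasma protein genes, a log2 ratio of 1.34 ± 0.07. The lists within each pool lay apart: the plasma protein median of 146 ± 5.66 TPM was close to the pooled red cell median and above that of the red cell regulators, 74.5 ± 0.180 TPM, while the hepatoblast median was 8.82 ± 0.682 TPM. The sums ran the other way, at 11103 ± 167 TPM for the red cell genes and 17398 ± 315 TPM for the hepatic genes. Their log2 ratio was -0.65 ± 0.05. Globins were left out of the red cell genes under both summaries, and the adult globins alone summed to 239900 ± 3107 TPM, above either sum. Alpha-fetoprotein, Afp, alone gave 29.6% ± 0.216 of the hepatic sum. The ratio lay on the same side in both libraries under either summary, and with 2 libraries the smallest p an exact sign-flip test can reach is 0.5, so no test was made.

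Every measured red cell gene of these lists was present at 10 TPM or more. Of 12 regulators, all reached 10 TPM and 5 reached 100 TPM. Klf1, the erythroid Krüppel-like transcription factor (chromosome 8, 84901928 to 84905291), had 448 ± 21.5 TPM. The transcriptional partner Lmo2 had 160.1 ± 3.16 TPM, the transcription factor gene Nfe2 had 141 ± 0.269 TPM and the erythropoietin receptor gene Epor had 131 ± 1.82 TPM. All 17 surface and membrane skeleton genes reached 10 TPM and 12 reached 100 TPM, with a list median of 174 ± 3.18 TPM. The anion exchanger gene Slc4a1 (chromosome 11, 102348824 to 102366203) led them with 789.5 ± 33.2 TPM, and the list also held Cd24a with 701 ± 18.7 TPM and the Rh blood group gene Rhd with 401 ± 0.990 TPM. Haem synthesis and iron genes had the highest median of the 3 lists, 314 ± 4.39 TPM, with 13 of 15 at 100 TPM or more. The ferrochelatase gene Fech had 672 ± 21.8 TPM, the erythroid aminolevulinate synthase gene Alas2 (chromosome X, 150547375 to 150570638) had 665 ± 20.3 TPM and the coproporphyrinogen oxidase gene Cpox had 584 ± 5.52 TPM.

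The hepatic lineage carried secreted plasma proteins at high levels and few of the enzymes of the mature hepatocyte. Of 31 plasma protein genes, 26 reached 10 TPM and 20 reached 100 TPM. Transferrin, Trf (chromosome 9, 103204001 to 103230444), had 2395 ± 53.4 TPM, the apolipoprotein genes Apoa2 and Apoa1 had 2159.8 ± 79.4 and 1211 ± 5.54 TPM, and the retinol carrier gene Rbp4 had 1199.9 ± 1.18 TPM. Fetub and Apoa4 were the 2 members under 1 TPM, at 0.435 ± 0.205 and 0.0200 ± 0.0283 TPM. Of 22 hepatoblast genes, 21 reached 1 TPM and 9 reached 10 TPM. Afp (ENSMUSG00000054932.6, chromosome 5, 90490737 to 90508907) stood far above the others with 5157 ± 131 TPM, and the transmembrane protein gene Dlk1 had 448 ± 7.45 TPM, the glypican gene Gpc3 had 232 ± 1.05 TPM and the keratin gene Krt18 had 62.9 ± 3.06 TPM. The transcription factor gene Onecut2 was the single hepatoblast member under 1 TPM, at 0.995 ± 0.120 TPM.

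Of 27 genes of mature hepatocyte metabolism, 16 lay under 1 TPM and none reached 100 TPM, with a list median of 0.160 ± 0.0141 TPM. Glutamine synthetase, Glul, had 86.5 ± 4.03 TPM, and the urea cycle genes Ass1 and Asl had 49.8 ± 0.488 and 33.6 ± 1.29 TPM. The adult cytochrome P450 gene Cyp3a11 had 0.0300 TPM in both libraries and Cyp2e1 had 0.0200 ± 0.0283 TPM. The median of the plasma protein list exceeded that of the mature hepatocyte list by 6.99 ± 0.07 on the log2(TPM + 1) scale. Afp exceeded albumin, Alb (chromosome 5, 90460897 to 90476602), 5.88-fold ± 0.222, with 6.04-fold in replicate 1 and 5.72-fold in replicate 2. Genes of bile duct cells lay below the plasma protein genes and above those of the mature hepatocyte, with 7 of 9 at 1 TPM or more and a median of 2.75 ± 0.785 TPM. Their leading member, the water channel gene Aqp1 with 24.5 ± 0.148 TPM, also belongs to the red cell membrane list. Sox4 had 8.57 ± 1.07 TPM, the duct keratin genes Krt7 and Krt19 had 5.09 ± 0.0636 and 4.48 ± 1.65 TPM, and Cftr and Muc1 had 0.0800 ± 0.0566 and 0.0550 ± 0.0778 TPM.

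Among the other blood lineages, platelet and granulocyte genes were well represented and lymphoid genes were almost undetected. Of 14 megakaryocyte genes, 12 reached 10 TPM, led by the platelet chemokine genes Pf4 (chromosome 5, 90772435 to 90773383) with 673 ± 70.9 TPM and Ppbp with 142 ± 6.53 TPM. The platelet integrin and glycoprotein genes Itga2b and Gp9 had 71.3 ± 3.78 and 35.6 ± 2.06 TPM. Of 12 granulocyte genes, 8 reached 10 TPM. The calcium-binding protein genes S100a8 and S100a9 had 189 ± 20.3 and 127 ± 25.7 TPM, myeloperoxidase, Mpo, had 178 ± 4.29 TPM and the granule protein gene Ngp had 34.2 ± 2.94 TPM. Of 21 macrophage genes, 19 reached 1 TPM and 10 reached 10 TPM. Lysozyme, Lyz2, had 98.6 ± 3.09 TPM, the haem oxygenase gene Hmox1 had 72.1 TPM in replicate 1 and 77.9 TPM in replicate 2, the iron exporter gene Slc40a1 had 71.6 ± 0.389 TPM and the complement gene C1qb had 45.1 ± 0.778 TPM. The macrophage receptor genes Cd163 and Vsig4 had 0.0450 ± 0.0071 and 0.0250 ± 0.0354 TPM.

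All 18 stem and progenitor genes reached 1 TPM, and their median was 5.00 ± 0.530 TPM. Cd34 had 23.0 ± 1.07 TPM, the stem cell factor receptor gene Kit had 21.5 ± 0.113 TPM and the homeobox gene Meis1 had 20.6 ± 0.0424 TPM. Of 8 mast cell genes, 3 reached 1 TPM. These were Gata2 with 12.2 ± 1.47 TPM, which is also a progenitor gene, the histidine decarboxylase gene Hdc with 5.29 ± 0.247 TPM and the carboxypeptidase gene Cpa3 with 3.27 ± 0.403 TPM, while Ms4a2, Tpsb2 and Mcpt8 had 0.305 ± 0.191, 0.150 ± 0.127 and 0.0850 ± 0.120 TPM. Of 15 lymphoid genes, 14 lay under 1 TPM. The B-cell receptor component Cd79b had 3.97 ± 0.707 TPM, the surrogate light chain gene Vpreb1 had 0.680 ± 0.0141 TPM, the interleukin receptor gene Il7r had 0.365 ± 0.163 TPM and the early B-cell factor Ebf1 had 0.280 ± 0.0849 TPM. Cd79a had 0.0750 ± 0.0354 TPM.

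Vessel and connective tissue genes were present at moderate levels. All 17 endothelial genes reached 1 TPM, with Egfl7 at 94.4 ± 8.52 TPM, Oit3 at 29.2 ± 3.08 TPM and the sinusoidal scavenger receptor genes Stab2 and Stab1 at 24.6 ± 2.88 and 23.2 ± 0.438 TPM. Of 18 mesenchymal and stellate cell genes, 17 reached 1 TPM and 10 reached 10 TPM. The collagen genes Col3a1, Col1a1 and Col1a2 had 161 ± 0.346, 121 ± 10.2 and 75.4 ± 5.30 TPM, the intermediate filament gene Vim had 98.1 ± 3.94 TPM, and the pericyte gene Rgs5 had 0.825 ± 0.0919 TPM. Of 8 mesothelial genes, 7 reached 1 TPM, with Podxl at 19.9 ± 0.856 TPM, Alcam at 7.42 ± 0.615 TPM, Upk3b at 5.80 ± 0.0212 TPM, the transcription factor Wt1 at 5.80 ± 0.368 TPM and Msln at 0.235 ± 0.0212 TPM. Of 16 niche factors, which are secreted or surface signals to blood progenitors, 12 reached 1 TPM. The chemokine gene Cxcl12 had 48.6 ± 0.0849 TPM, the stem cell factor gene Kitl had 14.8 ± 2.28 TPM and Tgfb1 had 11.6 ± 0.403 TPM, and Il7 and Fgf1 had 0.385 ± 0.0919 and 0.385 ± 0.0495 TPM.

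Genes of neighbouring and other organs were low. Of 12 gut, pancreas and lung genes, 11 lay under 1 TPM, with the stomach homeobox gene Barx1 at 6.28 ± 0.417 TPM, Vil1 at 0.730 ± 0.0707 TPM, Cpa1 at 0.605 ± 0.219 TPM, Pdx1 at 0.130 ± 0.113 TPM and Cdx2 at 0.0150 ± 0.0212 TPM. Ptf1a had 0 counts in both libraries. Of 10 cardiac genes, 7 reached 1 TPM, and these included the atrial light chain gene Myl7 with 18.5 ± 0.410 TPM, the cardiac actin gene Actc1 with 12.4 ± 6.65 TPM, Myl4 with 2.07 ± 1.16 TPM and Tnnt2 with 2.04 ± 1.07 TPM. Myh6 and Nkx2-5 had 0.810 ± 0.240 and 0.135 ± 0.0354 TPM. Of 10 neural genes, 8 lay under 1 TPM, with Gap43 at 6.72 ± 1.03 TPM, Map2 at 1.05 ± 0.255 TPM, Stmn2 at 0.805 ± 0.106 TPM, Tubb3 at 0.490 ± 0.212 TPM, Elavl4 at 0.470 ± 0.240 TPM and Elavl3 at 0.0150 ± 0.0071 TPM. Of 9 skeletal muscle genes, 5 lay under 1 TPM. The fast light chain gene Mylpf had 33.1 ± 2.18 TPM, the muscle actin gene Acta1 had 2.92 ± 1.63 TPM, the myogenic factor genes Myod1 and Myf5 had 0.740 ± 0.622 and 0.255 ± 0.247 TPM, and Tnnc2 had 1.04 ± 0.693 TPM. The myogenic factor gene Myog had 0.900 TPM in replicate 1 and 4.10 TPM in replicate 2.

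Proliferation genes were high throughout. All 20 cell cycle genes reached 10 TPM and 18 reached 100 TPM, with a median of 211 ± 1.70 TPM. The ribonucleotide reductase gene Rrm2 had 453 ± 13.7 TPM, Birc5 had 311 ± 2.64 TPM, the replication clamp gene Pcna had 299 ± 3.34 TPM and the replication helicase gene Mcm6 had 288 ± 0.587 TPM. Of 14 imprinted growth genes, 12 reached 10 TPM, with Dlk1 as above, the cell cycle inhibitor gene Cdkn1c at 370.1 ± 8.17 TPM, Mest at 316 ± 6.55 TPM and the insulin-like growth factor gene Igf2 at 306 ± 12.8 TPM. All 15 glycolysis and hypoxia genes reached 1 TPM and 7 reached 100 TPM, among them Ldha with 1452 ± 68.2 TPM, Gapdh with 1287 ± 48.1 TPM, Eno1 with 1081 ± 62.2 TPM and Aldoa with 471 ± 28.9 TPM. Of 14 sterol synthesis genes, 13 reached 10 TPM, with Fdps at 241 ± 3.88 TPM, Hmgcs1 at 90.4 ± 3.66 TPM, Sqle at 77.9 ± 3.26 TPM and Idi1 at 76.2 ± 0.629 TPM. Of 12 immediate early and heat shock genes, which respond to handling and stress, 4 reached 10 TPM. These were Dnajb1 with 56.5 ± 2.92 TPM, Ier2 with 30.9 ± 0.516 TPM, Junb with 15.2 ± 0.226 TPM and Jun with 10.1 ± 0.127 TPM, while Hspa1b and Fosb had 0.135 ± 0.0636 and 0.0350 ± 0.0071 TPM.

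Mitochondrial messages had a median of 775 ± 68.4 TPM over 13 genes. The highest were mt-Atp6 at 4379 ± 1.03 TPM, mt-Atp8 at 3283 ± 126 TPM, mt-Nd1 at 1699 ± 37.5 TPM and mt-Co2 at 1355 ± 98.8 TPM. The genes mt-Atp6 and mt-Atp8 overlap and the posterior SD of mt-Co2 was 10.2% of its count, so their levels are uncertain. Of 11 replication-dependent histone genes, whose messages mostly lack a poly(A) tail, 7 reached 10 TPM, with Hist1h4d at 109.5 ± 4.10 TPM, Hist1h2bc at 63.2 ± 0.0071 TPM, Hist1h2ab at 58.9 ± 0.141 TPM and Hist1h1c at 47.8 ± 0.0778 TPM. Hist1h2ac and Hist1h4a had 0.910 ± 0.212 and 0.575 ± 0.290 TPM. Histone genes are close copies of each other, so their separate levels are uncertain. The pools held embryos of both sexes, and the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had 18.3 ± 2.30, 11.6 ± 1.87, 6.42 ± 0.856 and 3.54 ± 0.262 TPM beside 9.23 ± 1.40 TPM of Xist, the RNA that silences an X chromosome in females. Across the lists, 15 of 31 had a median of 10 TPM or more. The medians of the erythroid, haem, plasma protein and cell cycle lists lay above all of 10000 random lists of protein-coding genes of the same size. The same held for both globin lists and for the imprinted growth, glycolysis with hypoxia and mitochondrial lists, so this rank is not particular to blood or liver genes. The mature hepatocyte, lymphoid and gut, pancreas and lung medians lay at the 5.42, 6.33 and 2.41 percentiles of the random lists.

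**Figure D2:**
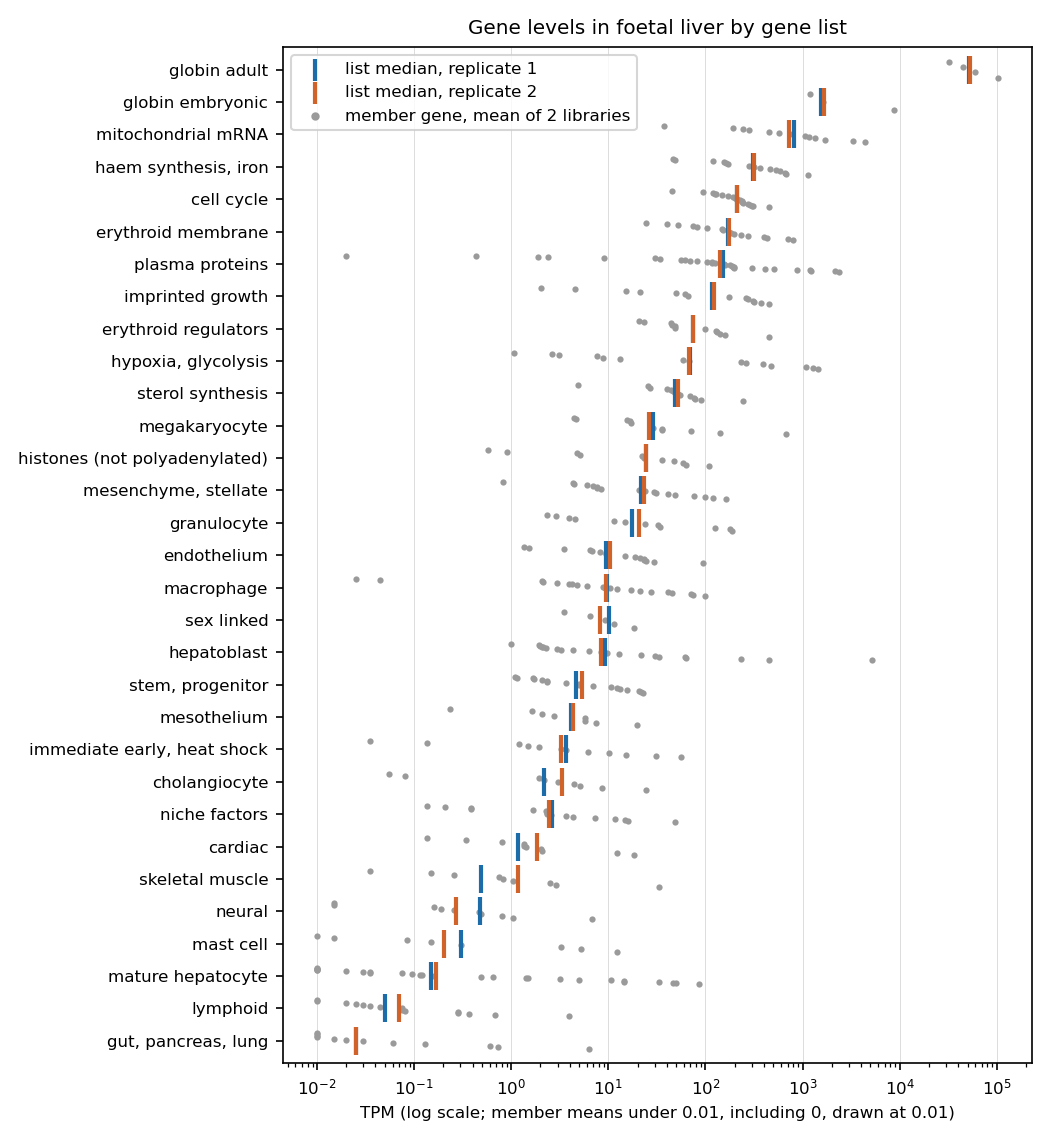
Median TPM of each of the 31 gene lists on a log axis, with a vertical tick for each library. Points are the member genes at their mean of the 2 libraries. Adult globins lead at 52542 TPM, and the gut, pancreas and lung list is lowest at 0.0250 TPM.

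Transcript use was examined in 25 genes chosen for red cells, liver or other tissues, of which 24 have more than 1 annotated transcript. Pklr has upstream and downstream promoters that serve the red cell and the liver pyruvate kinase. It gave 71.2% ± 1.27 of its TPM to the 2 transcripts starting at 89136142 to 89136174 on chromosome 3. The 3 starting at 89136572 to 89136623 held 28.8% ± 1.27. The upstream share held 15.9% ± 0.127 from Pklr-205, annotated as a processed transcript and not as protein-coding, with 175 and 169 counts. The leading coding transcripts of the 2 starts, Pklr-201 and Pklr-202, held 55.3% ± 1.40 and 26.6% ± 1.15. Hnf4a, a hepatocyte transcription factor, gave 90.6% ± 3.44 to Hnf4a-202, from the downstream start at 163547187 on chromosome 2, and 9.41% ± 3.44 to Hnf4a-205, from the upstream start at 163506808. The latter rested on 16.6 and 8.86 counts in replicates 1 and 2, with shares of 11.8% and 6.98%. Alad gave 98.5% ± 0.137 to Alad-201, and Pkm gave 94.8% ± 0.0673 to Pkm-201.

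In 14 of the 24 genes at least 2 transcripts held 10% or more of the gene in both libraries. They included Pklr, Ank1, Bcl2l1, Cebpa, Epb41, Fech, Fn1, Igf2, Kit, Nfe2, Ptprc, Runx1 and Tpm1. The membrane skeleton gene Epb41 gave 45.3% ± 1.04 to Epb41-215, annotated as a processed transcript and not as protein-coding. It gave 15.1% ± 0.852 to the next most abundant transcript. The ankyrin gene Ank1 gave 33.2% ± 0.520 to Ank1-206 and 18.1% ± 1.95 to Ank1-207. Fech gave 44.6% ± 1.07 to Fech-201 and 18.4% ± 1.41 to Fech-207, which is annotated as subject to nonsense-mediated decay. The survival gene Bcl2l1 gave 45.3% ± 1.89 to Bcl2l1-201 and 36.8% ± 0.144 to Bcl2l1-202. Kit gave 39.7% ± 2.20 to Kit-204, 33.1% ± 2.73 to Kit-201 and 20.0% ± 0.13 to the retained intron transcript Kit-208. Nfe2 gave 55.4% ± 2.49 to Nfe2-201 and 15.7% ± 2.26 to Nfe2-205. Cebpa gave 83.9% ± 4.81 to Cebpa-201 and 16.1% ± 4.81 to Cebpa-202. Fn1 gave 34.4% ± 2.13 to Fn1-201 and 31.7% ± 0.336 to the retained intron transcript Fn1-202. Igf2 gave 36.8% ± 3.00 to Igf2-203 and 34.2% ± 2.25 to Igf2-208, which is also annotated as a processed transcript. Runx1 gave 25.9% ± 0.623 to Runx1-201 and 24.5% ± 2.39 to Runx1-202. Tpm1 gave 27.0% ± 0.270, 25.9% ± 1.54 and 25.1% ± 0.539 to its 3 most abundant transcripts. The leading transcript was the same in both libraries in 21 of the 24 genes, the exceptions being Igf2, Ptprc and Runx1. Ptprc differed most, with Ptprc-203 at 24.0% in replicate 1 and 56.4% in replicate 2. Shares also depended on which transcripts the annotation holds: with M4, Fech-201 and Cebpa-201 each had 100% and Kit-204 had 51.4%, although the leading transcript was the same as with M21 in 18 of the 19 genes with several transcripts in both annotations. Transcript shares divide reads that transcripts have in common, so they carry the uncertainty of that division as well as the spread between libraries.

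**Figure D3:**
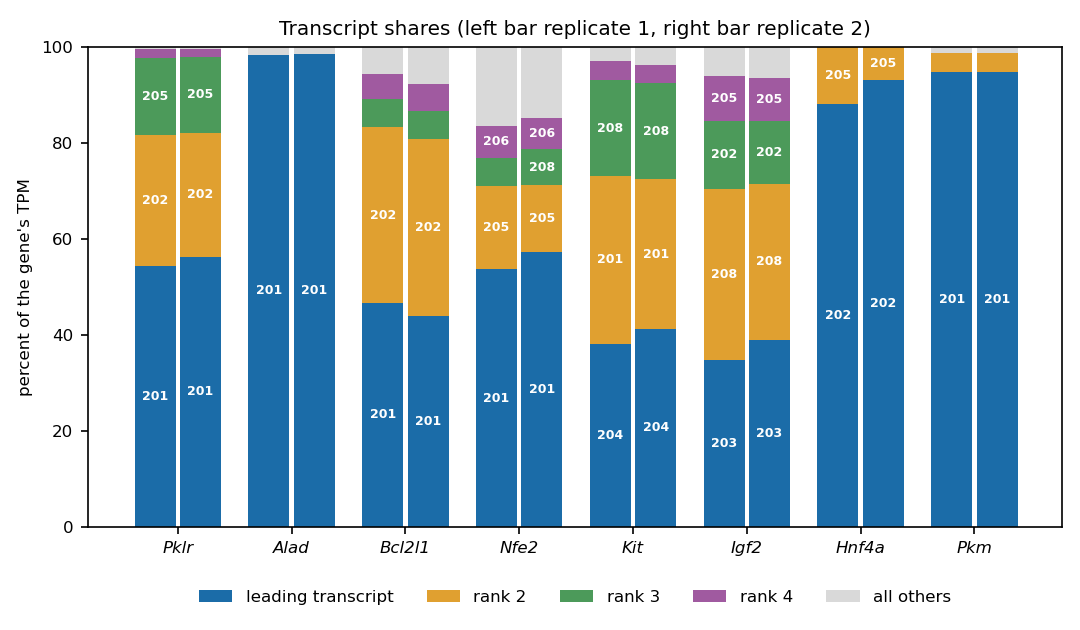
Share of each gene's TPM, in percent, given to its leading transcripts in the 2 libraries. Alad-201 takes 98.5% of Alad and Hnf4a-202 takes 90.6% of Hnf4a.

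The 2 pools were compared to see which genes and programmes differed between replicate libraries, a comparison of libraries and not of conditions. Skeletal muscle genes were higher in replicate 2: 6 of the 7 members with a mean of at least 10 counts passed 2-fold and counting error, and the list median was 3.09-fold, a log2 ratio of 1.63. Myog, a regulator of muscle differentiation (ENSMUSG00000026459.5, chromosome 1, 134289989 to 134292548), had 41 and 173 counts, a log2 ratio of 2.18 with a 95% interval of 1.69 to 2.72. Myod1 and Myf5 had log2 ratios of 1.97 and 2.38, Tnnc2 1.63, Acta1 1.27 and Myh3 1.22, whereas Mylpf, the most abundant member, had 0.14 and did not pass. Of the 6, only Myog, Acta1 and Myh3 had a mean of at least 100 counts. Calls below that, as for Myod1 (17 and 63 counts) and Myf5 (5 and 26 counts), can include false ones. The list median was the ratio of Tnnc2, which rested on 9.39 and 27.81 counts, with a 95% interval of 0.63 to 3.02. Of 9 cardiac genes, 4 passed with higher counts in replicate 2, namely Actc1 and Myh7 and, at means under 100 counts, Myl4 and Tnnt2, and Myl7 had a log2 ratio of -0.04. Myh7, a slow muscle and heart myosin on chromosome 14, had 66.3 and 217 counts, a log2 ratio of 1.82 with an interval of 1.43 to 2.25. The eosinophil-associated ribonuclease genes Ear1, Ear6 and Ear2 had log2 ratios of 1.77, 1.72 and 1.64. They belong to a family of close copies, and the posterior SDs of their counts were at most 1.16.

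Few abundant genes differed. Of 17343 genes with a mean of at least 10 expected counts, 407 (2.35%) differed by over 2-fold and beyond counting error, 235 higher and 172 lower in replicate 2, and their median mean count was 18.95. Among 12047 genes with a mean of at least 100 counts there were 18, of which 16 were higher and 2 lower in replicate 2. The 2 lower genes were 1700047I17Rik2, with 211 counts in replicate 1 and 0 in replicate 2, at least 65.1-fold lower against a floor of 3 counts in a library, and Gvin1, with 142 and 62.1 counts and a log2 ratio of -1.08. The largest difference upward was mt-Nd4l, with 0 and 444 counts, at least 160.1-fold higher against the same floor. The posterior SDs of its counts were 113 and 223, it overlaps mt-Nd4, and the posterior SDs were 130.3 and 111 for 1700047I17Rik2 and 22.7 and 24.5 for Gvin1, so all 3 are uncertain. A posterior SD over 10% of the count was found in 6 of the 18 genes and in 177 of the 12047. Scaling by the spike-ins moved all log2 ratios by -0.12 and turned the split of calls to 173 higher and 239 lower, or 42.0% higher against 57.7%.

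Across all 55536 genes log2(TPM + 1) had a Pearson r of 0.996 and a Spearman rho of 0.928 between the libraries, across genes that are not independent replicates. The median absolute log2 ratio was 0.10 over the 17343 genes, the ratios of 6342 genes with a mean of at least 1000 counts had an SD of 0.09, and the common biological coefficient of variation was 4.51%. A chi-square of the counts against sampling noise, divided by its degrees of freedom, was 3.74. With a single library per pool, differences between the pools cannot be told apart from those of library preparation, PCR or read division. In the spike-ins, 86 of 96 were detected in each library, they took 2.88% and 3.13% of counts (3.01% ± 0.176), and the log-log slope of their TPM between libraries was 0.972 over the 82 found in both.

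Of the 31 lists, 13 had a median log2 ratio outside the central 95% of 10000 random lists matched on mean expression. By chance 1.55 would be outside if the members of a list varied independently, which was not tested. After skeletal muscle, the higher medians in replicate 2 were 0.60 for cardiac, 0.31 for sex-linked, 0.22 for granulocyte and 0.15 for mesenchymal genes. Of the 9 cardiac genes, 6 had ratios above 0 and 3 below, and 4 passed 2-fold. Myl7 and Myh6 had -0.04 and 0.28, with intervals that include 0. Whether the cardiac difference is separate from that of the skeletal muscle genes was not tested. Those of embryonic globins (0.10), sterol synthesis (0.09), red cell membrane (0.04), imprinted (0.04) and haem synthesis genes (0.03) were also higher than those of random lists. Spike-in scaling, which shifts every list and random list alike, puts these 5 below 0, at -0.02, -0.03, -0.08, -0.08 and -0.09, with unchanged percentiles. With random lists matched also on transcript length, the imprinted list lay inside, at percentile 95.3, and hepatoblast genes, inside at 2.59 with a median of -0.06, lay outside at 2.07. Lower medians in replicate 2 were -0.37 for neural, -0.13 for megakaryocyte and -0.10 for glycolysis genes, and the neural list had too few genes to be placed at a mean of at least 100 counts. In the granulocyte list 11 of 12 genes had ratios above 0, among them S100a9 with 0.42 and S100a8 with 0.22, and in the megakaryocyte list 13 of 14 lay below 0, among them Pf4 with -0.22. In the sex-linked list Eif2s3y, Ddx3y, Uty and Kdm5d had log2 ratios of 0.34, 0.36, 0.23 and 0.31, and Xist had -0.31. The other 18 lists lay inside, with medians from -0.14 for mast cell genes to 0.20 for gut, pancreas and lung genes. No single gene of the granulocyte, megakaryocyte or sex-linked list passed 2-fold. Random lists describe these libraries and give no test of the pools.

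**Figure D4:**
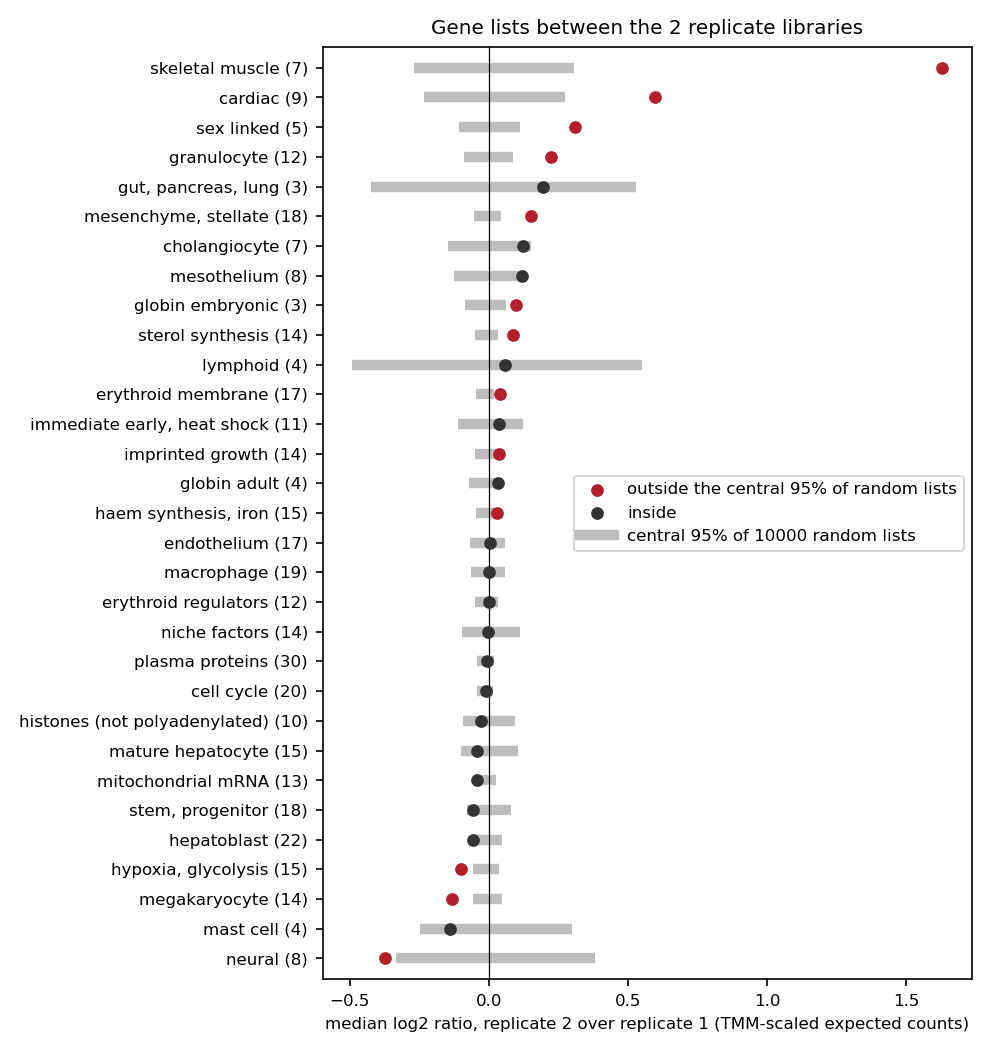
Median log2 ratio of replicate 2 over replicate 1 for each gene list, with the central 95% of matched random lists as a line. Skeletal muscle lies at 1.63 and neural genes at -0.37, and embryonic globin, sterol, red cell membrane, imprinted and haem medians lie below 0 when libraries are scaled by the spike-ins, which shifts all lists alike.

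Each library was quantified against the GENCODE M4 and M21 annotations, and the comparison shows which gene levels depend on the annotation. The red cell regulator Sox6 had 48.3 TPM with M21 and 17.7 TPM with M4, a log2 ratio of 1.40 ± 0.14 on the log2(TPM + 1) scale. Gata2 (0.78 ± 0.13), the growth factor gene Hgf (0.74 ± 0.08) and the membrane skeleton gene Dmtn (0.65 ± 0.01) were also higher with M21, and the histone genes Hist1h2ac (-2.09 ± 0.01), Hist1h4d (-1.86) and Hist1h2bc (-0.96) were lower. These were the 7 of 348 list genes at 1 TPM or more that differed by over 1.5-fold in both libraries. Among all 13235 shared genes at 1 TPM or more, 729 (5.51%) did so, 529 higher and 200 lower with M21. The share was 4.96% of protein-coding genes and 15.7% of pseudogenes.

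The genes with the largest differences between annotations were mostly pseudogenes. Lower with M21 were the pseudogenes Gm10925 (0.145 ± 0.120 against 102 ± 30.8 TPM), Gm8355 (0.700 ± 0.269 against 141 ± 29.4 TPM) and Gm6565 (0 against 60.4 ± 1.86 TPM), and the protein-coding genes Usp50 (2.10 ± 0.120 against 247 ± 2.00 TPM) and Gm49342 (0 against 64.9 ± 1.31 TPM). Higher with M21 were the pseudogenes Gm10774 (86.4 ± 8.25 against 0 TPM), Gm6361 (58.9 ± 1.72 against 0 TPM), Gm8741 (50.1 ± 0.587 against 2.08 ± 1.53 TPM) and Gm5616 (80.6 ± 0.516 against 4.46 ± 0.665 TPM), and the kinase gene Ulk4 (43.3 ± 1.15 against 0.595 ± 0.0778 TPM). Pseudogenes share reads with their parent genes, so these levels are uncertain under either annotation. Both quantifications come from the same 2 libraries, so the comparison concerns the annotation and holds no independent replicate.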

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

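No test or alternative in this part was chosen after seeing the results. The entries with bare numbers as identifiers, 26248 under M21, were left out of the analyses and held 53.3 expected counts in replicate 1 and 44 in replicate 2. These sums lie above the floor of 3 counts and make up 0.000139% and 0.000124% of all expected counts. No cause was tested, since the sources do not explain the entries, and no gene result above rests on them.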

How the results depend on the processing

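Length-matched random lists, protein-coding genes only and members with a small posterior SD were chosen after seeing the data, and all other alternatives were fixed beforehand. The 407 genes differing between libraries became 753 without a count filter, 18 at a mean of at least 100 counts and 244 among protein-coding genes only, and filtering removes genes by construction. Scaling by DESeq2, spike-ins or total count gave 408, 412 and 407. The programme log2 ratio of 1.34, with globins left out of the red cell genes, turned to -0.65 with summed TPM. The ratio of medians was 1.22 with M4 and 1.24 with members at 1 TPM or more, and the cause was not tested. The embryonic alpha share of 1.08% became 1.52% in expected counts, where lengths are not divided out. The 729 genes differing between annotations became 335 at 2-fold, which is stricter by construction, and 381 with expected counts; the cause of the latter was not tested. Leaving out either library gave 1.29 to 1.40 for the programme ratio, 9.43% to 9.94% and 1.05% to 1.10% for the embryonic beta and alpha shares, 5.72 to 6.04 for Afp over Alb and 6.93 to 7.04 for plasma over mature hepatocyte genes. With M4, 68 of 152 named gene levels and 16 of 31 list medians moved by more than 1 SD of the 2 libraries, and rescaling raised all 31 medians. Of the lists, 13 lay outside random lists with DESeq2, spike-in scaling, at least 100 counts and length matching, and 14 with M4; hepatoblast genes were outside at percentile 2.30 with at least 100 counts, 2.46 with M4 and 2.07 with length matching, and imprinted genes were inside at 95.3 with length matching. At 100 counts the neural, lymphoid and gut, pancreas and lung lists (3 lists) had under 3 members and gave no value, so the neural difference has no counterpart there. No paired analysis was possible because the labels give only 1 group.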

Other observations

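The tests of library scaling, of the Y-linked genes of the fixed list and of the summed adult beta globins were chosen after the results were seen, and those of further muscle genes, skin and cartilage genes, other Y-linked genes and long genes before their values were read. Among genes outside the naming rule, chosen after their values were seen, the eosinophil granule genes Prg2 and Epx were higher in replicate 2. Prg2, the major basic protein gene, had 561 and 1478 counts, a log2 ratio of 1.51 with a counting interval of 1.37 to 1.65. Epx, the eosinophil peroxidase gene, had 95 and 239 counts, a log2 ratio of 1.44. Ear1, Ear2 and Ear6 moved the same way, and no list of eosinophil genes was tested.

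Other genes chosen after their values were seen set limits to the programmes above. The mature hepatocyte genes Cyp2c29, Cyp2f2, G6pc, Mup3 and Sds had 0 counts in both libraries. Entries with an effective length of at most 50 bases took 0.937% and 0.960% of TPM from 0.0139% and 0.0142% of counts, so TPM of very short genes is to be read with the count beside it.

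Skeletal muscle genes were higher in replicate 2, and muscle tissue carried along at dissection could account for this, since nothing in the labels would have removed it. Among muscle genes outside the fixed list, 19 of 20 had ratios above 0 and the median log2 ratio was 0.98, against bounds of at least 1 for and under 0.5 against set beforehand, so the test cannot tell. That median lay at percentile 100 of matched random lists. Of the 20 genes, 8 were called higher and 0 lower, some at means under 100 counts, where calls can be false. The difference thus extended to other muscle genes, but a higher ratio cannot show whether dissection caused it. Of the 24 genes of this further list, 7 reached 1 TPM and 0 stood in another list. The choice among the 4 scalings does not account for it, and the lowest median of the fixed list under them was 1.51. A change of scaling moves every log2 ratio alike, by -0.12 with the spike-ins, so this outcome followed from the size of that shift. Skin, cartilage and limb genes had a median of 0.24 over 11 genes and cannot tell whether other tissue came along. No biological explanation was tested, as there is a single group.

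The Y-linked genes were higher and Xist lower in replicate 2, and a larger share of male embryos in that pool may account for it. All 4 Y-linked genes of the fixed list had log2 ratios above 0 and Xist had -0.31, but these are the genes that gave the pattern, so this cannot tell. Outside the fixed list 0 protein-coding Y-linked genes had a mean of at least 10 counts and a posterior SD under 10%, so no separate test was possible and the explanation stays open. A bias against long transcripts in replicate 2 could lower Xist, but 124 genes over 8000 bases had a median log2 ratio of 0.042. Over 11439 genes the ratio rose with length (Spearman rho 0.155). These values argue against a general bias of that kind, and they cannot exclude an effect on Xist alone. No biological explanation was tested, as there is a single group.

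The adult beta globins Hbb-bs and Hbb-bt differed between annotations by 27.3% and -30.8% (M21 against M4). Reads shared by the near-identical copies and divided differently are a candidate explanation: their sum differed by only -1.48%, which fits. Summed beta globin shares are therefore less exposed to the annotation than either gene alone. Within the alpha pair M21 gave 44847 TPM for Hba-a1 and M4 gave 46425 TPM.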
